A study of Caenorhabditis elegans with 2 samples.

How the data were processed

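The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of SMA-9, a zinc-finger transcription factor of the Schnurri family that acts in the DBL-1 pathway, a BMP-like signalling pathway of Caenorhabditis elegans. Per the labels, whole hermaphrodite larvae of strain LW1254 were collected at the L2 stage, 22 hours after synchronization by starvation at the L1 stage. The strain carries an integrated transgene with sma-9 fused to GFP and an unc-119 rescue marker, and an antibody against GFP was used. The labels give 1 group with 2 biological replicates and name no treatment, so no contrast between conditions could be made. The control experiment that the labels point to was not analysed here.

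The authors deposited 8 peak lists, 4 on each of the genome builds ce10 and ce11. Per the file headers, each replicate's list of peaks and background was derived from its own alignments and 1 further file, which the control-normalized signal tracks also use, a pooled list was derived from both replicates, and the list that passed the irreproducible discovery rate (IDR, a test of whether peaks keep their rank between replicates) was derived from these 3. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each line carries the authors' peak signal, which is the caller's own value and has no fixed range, and a −log10 q-value, also as deposited by the authors. The signal was used to rank and describe peaks within a list. Signals of different lists were set side by side only in the correlation of the replicates, in the match between builds and for the mitochondrial peaks of replicate 2. The −log10 q-value is capped, and all 7065 IDR peaks of ce11 held the same highest value of 4.17, so it could not rank them. Ranks within replicate 2 count its mitochondrial peaks. The summit is the position the authors' list gives inside each peak. No read counts are in the lists, so the depth per sample is unknown, and the number of replicates limits the precision. The Wilson intervals below cover counting error over peaks or genes, which are not independent replicates.

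The main build was ce11, which is WBcel235, and coordinates below are 1-based on it. No coordinates were converted between builds. Genes came from the Ensembl 115 annotation, with 19973 protein-coding genes on the 6 nuclear chromosomes and 29314 distinct annotated 5' ends. Many annotated 5' ends in this species are trans-splice sites, so a distance from them is not a distance from the site of transcription initiation. A gene was called bound if an IDR summit lay within 1000 bp on either side of any of its annotated 5' ends. A divergent promoter can therefore give a call to both of its genes.

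Replicates were compared by the share of the 7065 peaks of highest signal in each that shared at least 1 bp with the other's, after leaving out mitochondrial peaks, against 100 shuffles of peak positions on the same chromosome. Signal was compared by Pearson's correlation of log2 signal and Spearman's correlation across IDR peaks, using the replicate peak that contained the IDR summit. Summit locations were tested against 1000 draws of random positions on the same chromosomes with a permutation test, for which 0.002 is the smallest two-sided p. Each of 19 gene lists fixed before the data were examined was tested with Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists at 0.05. One listed symbol, emo-1 of the ER and secretion list, was not found in the annotation. Motifs were counted on both strands in the 101 bp around each summit and in an equal window centred 250 bp away on a random side, and tested with an exact binomial test on the peaks where only 1 of the windows held the motif. There were 9 motifs and, separately, 2080 6-mers with their reverse complements, each adjusted within its family.

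The tests were tested on simulated data. With 20 sets of simulated peaks that favoured no list, Fisher's exact test called 9 of 380 list tests. Genes with more annotated 5' ends are called more often by chance. A permutation test among genes with the same number of 5' ends was therefore added after the data were seen, and it called 5 of 380. The threshold of 0.05 applies after adjustment over the lists, and the number of sets with any call is not given. The shares of 380 therefore cannot be read against 0.05, and they do not show that the list p-values hold for these data. A planted list of 40 genes with a peak placed at 40% of its members was called in 11 of 20 simulations. A list of 20 genes with the same share was called in 6 of 20, and a list of 20 with a peak placed at 20% in 0 of 20. Planted genes received none of the other peaks placed near gene 5' ends, so the excess was smaller than the placed share. A 6-mer planted in 5% of windows ranked 1 of 2080 by p, and 7 6-mers were called in that run. The permutation test of summits near 5' ends called 2 of 20 sets of random positions at 0.05.

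Genes named in the text followed a rule fixed before the data were examined. They are protein-coding genes within 1000 bp of the 10 strongest summits, up to 3 bound members of each list with the highest signal and up to 2 unbound members first in the alphabet, the 5 best 6-mers, and a fixed set of 12 genes of the pathway, the transgene and related targets. Other genes are said to have been chosen after their values were seen. The other settings tried were windows of 500 and 2000 bp, the 3532 IDR peaks of higher signal, each replicate alone, a background of genes with a symbol, a background stratified by distance to the upstream gene, stricter definitions of shared peaks, other motif windows and the ce10 lists. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.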

Results

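SMA-9 binding was mapped in L2 larvae by ChIP-seq of a GFP fusion, in 2 biological replicates of 1 group. The IDR list held 7065 peaks on ce11, with a median width of 270 bp and a median signal of 109 (range 61.96 to 2844). These peaks were the first 7065 of the 30000 calls of the pooled list by signal. The depth of the libraries is unknown from peak lists.

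The strongest peak lay on chromosome V at 6246356 to 6246899, 210 bp upstream of a 5' end of dmd-7, a gene with a DM DNA-binding domain. Its pooled signal was 2844, and it ranked 1 in replicate 1 and 2 in replicate 2, whose ranks also count mitochondrial peaks, 1 of them above it. The pqn-41 gene on chromosome III, which encodes a glutamine-rich protein, held 3 of the 10 strongest peaks in its introns, at 1926436 to 1926757, 1925001 to 1925583 and 1920982 to 1921737, with signals of 1944, 1715 and 1677. The promoter of rpl-3, a ribosomal protein gene, had a signal of 1829 at III 3867449 to 3867691. A peak at V 11572822 to 11573207 (signal 1687) lay upstream of both the nuclear receptor gene nhr-68 and H12C20.7, and a peak at II 10563467 to 10563675 (signal 1630) lay 162 bp upstream of cdc-48.1, which encodes an AAA ATPase of protein quality control. The other 3 of the 10 strongest peaks were intergenic at III 4281923 to 4282596 and X 6737422 to 6738097, and intronic in Y111B2A.12 at III 12612430 to 12612893. Like the pqn-41 peaks, they had no protein-coding 5' end within 1000 bp of the summit, and the genes pqn-41 and Y111B2A.12 were chosen after their values were seen.

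The sma-9 gene itself (WBGene00004862, X 10769282 to 10782973, forward strand) carried 10 IDR peaks in the gene or within 3000 bp of it, 3 of them among the 50 strongest of the genome. The strongest was intergenic at X 10766013 to 10766638, with a signal of 1495 and ranks of 20 and 13 in replicates 1 and 2. Inside the gene, peaks at 10772120 to 10772524, 10770955 to 10771483 and 10772787 to 10773056 had signals of 1062, 1014 and 649. The first and the last of these lay upstream of internal 5' ends and the other lay in an intron. Among the 10 peaks, those at 10767285 to 10767356 and 10768696 to 10768810 had no replicate 2 call at the summit. Downstream of 10773056 the gene held 11 calls of the pooled list and 0 IDR peaks. The transgene carries sma-9 sequence, so reads from the transgene and from the endogenous locus could not be separated in these lists.

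**Figure D1:**
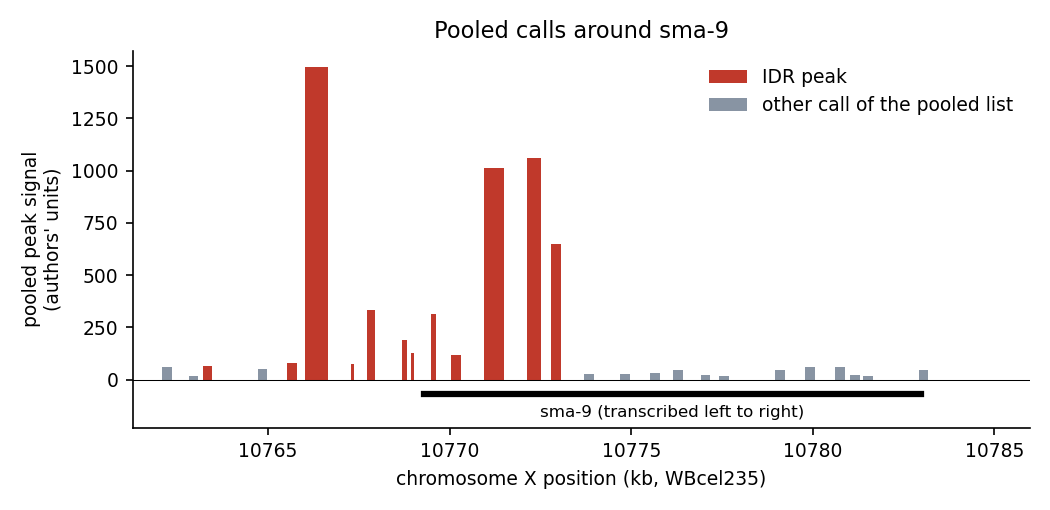
Pooled peak signal (y axis, the authors' units) against position on chromosome X in kb (x axis, WBcel235), with red bars for IDR peaks, grey bars for other calls of the pooled list and a black line for the sma-9 gene. The strong peaks, up to a signal of 1495, stand upstream of the gene and in its 5' part, and the rest of the gene holds 11 weaker calls.

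Replicate 1 was compared with replicate 2 to see how far the peaks recurred. Of the 7065 strongest nuclear peaks of replicate 1, 5283 overlapped 1 of the 7065 strongest of replicate 2, which is 74.8% (95% Wilson interval 73.8 to 75.8%). The share was 75.02% from replicate 2 to replicate 1 and 3.44% ± 0.224 (mean and SD of 100 shuffles) by chance, with a highest shuffled value of 3.98%. It was 79.4% among the 500 strongest peaks and 61.3% among the 20000 strongest. Of the IDR summits, 6727 (95.2%) lay inside a call in both replicates, and 71.7% inside a call among the first 7065 of both. Across the 6727 peaks the signals correlated with a Pearson's r of 0.776 on log2 values and a Spearman's rho of 0.707. The IDR list was derived from both replicates and equals the first 7065 calls of the pooled list by signal. The shares of IDR summits and the correlations are therefore not independent of how the list was chosen. The overlap of the strongest peaks of each replicate took only the number of peaks from it. Peaks are not independent replicates, so no p-value is given. The peaks at dmd-7 and rpl-3 ranked within the first 11 in each replicate.

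**Figure D2:**
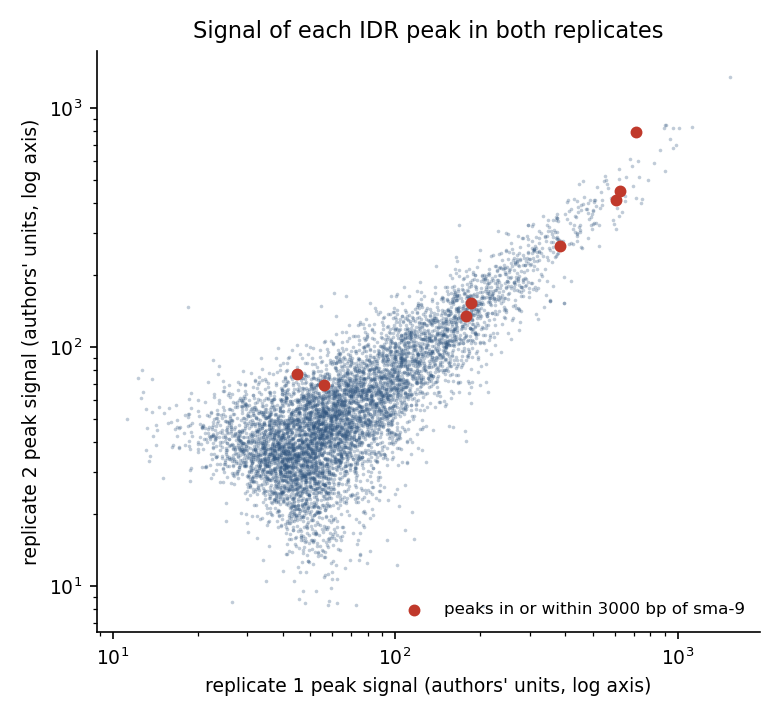
Peak signal of replicate 2 (y axis) against replicate 1 (x axis), both in the authors' units on log axes, for the 6727 IDR peaks with a call in both replicates, with peaks in or within 3000 bp of sma-9 in red. The points follow a rising band (Pearson's r of 0.776 on log2 values) that narrows towards strong peaks.

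Where summits lay relative to genes was compared with random positions. SMA-9 summits were most frequent in the 1000 bp upstream of protein-coding genes and scarce in coding exons. Upstream regions held 46.7% of IDR summits (95% Wilson interval 45.5 to 47.8%) against 22.1% ± 0.499 (SD of 1000 draws) of random positions, a ratio of 2.11. Coding exons held 2.34% against 20.9%, 3' UTRs 0.679% against 2.42%, and introns 19.5% against 28.0%, all lower than random. Among the peaks of higher signal coding exons held 1.16%. Intergenic sequence beyond the upstream regions held 26.2% against 22.1%. Each of these 5 classes differed by permutation test with an adjusted two-sided p of 0.0028, the smallest that the draws allowed. In 5' UTRs (1.36% against 1.11%) and other transcribed genes (3.33% against 3.43%) the permutation test found no difference at 0.05, with adjusted p of 0.0653 and 0.659. Counted on both sides of 5' ends, 55.1% of summits lay within 1000 bp, against 40.7% ± 0.574 at random (permutation test, two-sided p = 0.002 and one-sided p = 0.001, the smallest possible). The median distance to the nearest 5' end was 804 bp, 71.9% of summits lay on its upstream side, and 25.4% were more than 2000 bp from any.

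**Figure D3:**
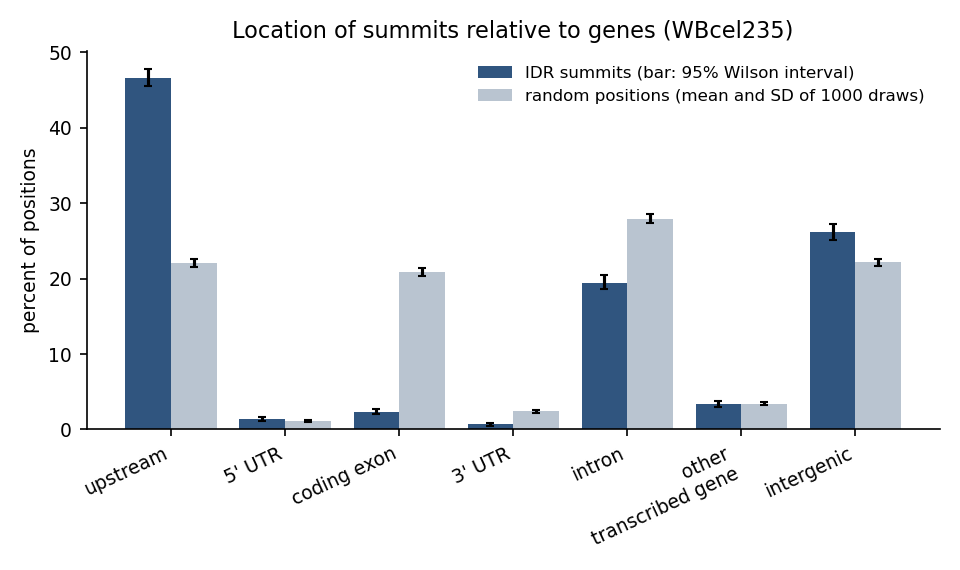
Percent of positions (y axis) in 7 location classes (x axis) for IDR summits, with 95% Wilson intervals, and for random positions, with the mean and SD of 1000 draws. Upstream regions hold 46.7% of summits against 22.1% of random positions, and coding exons 2.34% against 20.9%.

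Peaks were denser on the X chromosome and in the centers of the autosomes. The X chromosome held 1699 IDR peaks, 95.9 per megabase, against 65.0 per megabase over the autosomes, where the values ran from 57.5 on chromosome I to 74.1 on chromosome II. Random positions over the 6 chromosomes gave 1249 ± 33.8 (SD) on X, and the permutation test, added after the data were seen, gave a two-sided p of 0.002, its smallest value. The replicates taken alone had 96.8 and 91.4 peaks per megabase on X. The central 33.3% of the length of each autosome held 49.8% of autosomal summits against 33.3% ± 0.649 of random positions (permutation test, two-sided p = 0.002). Random protein-coding 5' ends, which are themselves denser in the centers, gave 39.001% ± 0.651, with the same p from the permutation test.

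By the rule of 1000 bp around 5' ends, 4030 of 19973 protein-coding genes (20.2%) were bound. The DBL-1 pathway list, the pathway in which SMA-9 acts, had 9 of 19 members bound (47.4%, Wilson interval 27.3 to 68.3%) against 20.2% of other genes. After sma-9, the strongest were sma-10, which encodes a receptor-binding membrane protein, with a signal of 311 at IV 274247 to 274403, and the Smad gene sma-2, also with a signal of 311, at III 8749495 to 8749784, 60 bp upstream of its 5' end. The Smad gene sma-3 (signal 69.2) and the type II receptor gene daf-4 (signal 116) were bound by weaker peaks. The ligand gene dbl-1 and the glypican gene lon-2 had no IDR peak in the gene or within 3000 bp of it. The Smad gene sma-4, the type I receptor gene sma-6, the downstream gene lon-1 and the chordin-family gene crm-1 were not bound by the rule, but had peaks within 3000 bp with signals of 138, 145, 202 and 247. The peaks of sma-6 and crm-1 lay past the 3' end of the gene. Those of sma-4 and lon-1 lay upstream, and that of lon-1 had no replicate 1 call at its summit. The list's odds ratio was 3.57 (95% interval 1.28 to 9.77), with an adjusted p of 0.0167 by Fisher's exact test. Without the 10 peaks at sma-9 it was 2.88 with an adjusted p of 0.0806 by the exact test. There sma-9 stayed in the list as an unbound member by construction, and a list without sma-9 was not tested. So this value cannot show whether the call rests on sma-9. Among genes with the same number of 5' ends the odds ratio was 2.60 with an adjusted p of 0.154 by permutation test. The call was also lost with a 500 bp window (3.21), with genes with a symbol as background (2.86) and without replicate 2 (2.91), and a 2000 bp window gave 5.69.

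Of the 7 genes of the DAF-7 pathway, a TGF-beta-like pathway that controls dauer entry, 5 were bound, led by the Smad gene daf-14 (signal 210), the Smad gene daf-3 (130.6) and daf-4, which is in both pathway lists. The ligand gene daf-7 and the Smad gene daf-8 were not bound and had no IDR peak within 3000 bp. The odds ratio was 9.90 (1.62 to 103.996) with an adjusted p of 0.0132 by Fisher's exact test. Its members have 3 annotated 5' ends on average against 1.47 for all genes, and among genes with the same number of ends the odds ratio was 10.2 with an adjusted p of 0.0912 by permutation test. A 500 bp window (odds ratio 4.12) and the peaks of higher signal (5.63) also ended the call, and a 2000 bp window gave 6.56.

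Ribosomal protein genes and genes of ER function and collagen secretion were bound more often than other genes. The other genes were not matched for expression, for these or any other lists, and no worm without the transgene was among the samples. An effect of expression level on these shares was not tested. Of the ribosomal protein genes 60 of 78 were bound (76.9%, interval 66.4 to 84.9%, odds ratio 13.4, adjusted p of 5.47e-26 by Fisher's exact test), led by rpl-3, rpl-15 (signal 1315) and rpl-20 (1163). The genes rpl-1 and rpl-10 were not bound. The list of ER and collagen secretion genes had 14 of 25 bound (odds ratio 5.05, 2.13 to 12.3, adjusted p of 0.00035 by Fisher's exact test). Its strongest were hsp-3, an ER chaperone of the BiP family, with a signal of 489 at 50 bp upstream of its 5' end, the COPII coat gene sec-24.1 (380) and xbp-1, a transcription factor of the unfolded protein response (316). The calnexin gene cnx-1 and the prolyl hydroxylase gene dpy-18 were not bound by the rule. Of the histone genes 20 of 72 were bound, led by his-37 (725) and by his-67 and his-68, which share a peak (366), while his-1 and his-12 were not bound. The histone list did not pass the exact test (odds ratio 1.52, adjusted p of 0.157).

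Members of the lists of lipid metabolism and of immunity were also bound more often. The lipid list had 15 of 28 members bound (53.6%, interval 35.8 to 70.5%, odds ratio 4.58, adjusted p of 0.00035 by Fisher's exact test). The strongest were acs-2, an acyl-CoA synthetase gene of fatty acid oxidation (signal 374), the nuclear receptor gene nhr-49 (305) and the desaturase gene fat-3 (264). The desaturase gene fat-6 had a signal of 161 and the nuclear receptor gene nhr-114 a signal of 76.0. The genes acdh-1 and elo-5 were not bound. Without replicate 2 the odds ratio of the lipid list was 7.23. The immunity list had 19 of 35 bound (54.3%, interval 38.2 to 69.5%, odds ratio 4.71, adjusted p of 5.28e-05 by Fisher's exact test), led by hlh-30, a transcription factor of autophagy and defence (280), the lysozyme gene lys-8 (191) and the C-type lectin gene clec-85 (190). The clec-85 summit lay past the 3' end of the gene, 770 bp downstream of an internal 5' end. The antimicrobial peptide genes abf-1 and abf-2 were not bound. The C-type lectin family as a whole, most of it outside this list, was bound less often than other genes, at 21 of 240. Both lists and the ER list kept their calls among genes with the same number of 5' ends, with adjusted p of 0.0146, 0.0013 and 0.0029 by permutation test.

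Collagens of the cuticle set body shape. Of the col genes 21 of 156 were bound (13.5%, interval 8.98 to 19.7%), with an odds ratio of 0.613 and an adjusted p of 0.0745 by Fisher's exact test. This list passed on the low side in either replicate taken alone (0.548 and 0.455), among the peaks of higher signal (0.351), with a window of 2000 bp (0.648) and against genes with a symbol (0.489). Among genes with the same number of 5' ends it did not pass, at 0.707 with an adjusted p of 0.255 by permutation test. Bound members included col-85 (signal 241), col-38 (196) and col-2 (159), and unbound ones col-101 and col-102. Of the collagen and cuticle genes known from body-shape mutants 5 of 20 were bound, among them dpy-10 (231), bli-6 (139) and sqt-3 (89.7), but not bli-1 or bli-2 (odds ratio 1.32, adjusted p of 0.647 by the exact test). With a 2000 bp window this list passed on the high side, at an odds ratio of 3.21 and an adjusted p of 0.0248 by the exact test, whereas it was 0.699 without replicate 1 and 0.834 among the peaks of higher signal. Of the molting genes 4 of 20 were bound, with myrf-1 (354), lin-42 (135) and noah-1 (128) strongest and acn-1 and bli-5 unbound (odds ratio 0.989, adjusted p of 1 by the exact test).

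Whole larvae hold all cell types, and no test compared the marker lists with each other. Body wall muscle markers were bound at 11 of 19 (57.9%, interval 36.3 to 76.9%, odds ratio 5.45, adjusted p of 0.0011 by Fisher's exact test), among them the troponin T gene mup-2 (signal 202), the myogenic factor gene hlh-1 (120) and the twitchin gene unc-22 (113), but not deb-1 or lev-11. Among the 3532 peaks of higher signal the muscle list lost its call, with an odds ratio of 1.41. Its odds ratio was 8.61 without replicate 1, 3.61 without replicate 2 and 14.02 with a 2000 bp window. Intestine markers were bound at 7 of 18, with pgp-1 (223), the GATA factor gene elt-2 (167) and the actin gene act-5 (159) strongest and asp-3 and cpr-5 unbound. Epidermis regulators were also bound at 7 of 18, with the GATA factor gene elt-1 (368) and the heterochronic genes lin-28 (326) and lin-14 (287) strongest and blmp-1 and bro-1 unbound. Both lists had an odds ratio of 2.52 and an adjusted p of 0.112 by the exact test. With a 2000 bp window both passed, at an odds ratio of 3.28, and without replicate 2 both passed at 4.01. The intestine list also passed without replicate 1 (3.18) and among the peaks of higher signal (3.76). Among genes with the same number of 5' ends the epidermis list was at 1.59 with an adjusted p of 0.649 by permutation test.

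Neuron markers were bound at 7 of 32 (odds ratio 1.11, adjusted p of 0.871 by the exact test), among them the synaptobrevin gene snb-1 (167), rab-3 (114.1) and egl-21 (103.6), but not cat-1 or cat-2. With a 2000 bp window the neuron list passed at 2.32 with an adjusted p of 0.0429 by the exact test, whereas it was 0.50001 among the peaks of higher signal and 0.915 without replicate 1. Pharynx markers were bound at 1 of 12, the FoxA gene pha-4 (80.3), and not at ceh-22 or ceh-6 (odds ratio 0.359, adjusted p of 0.608 by the exact test), and the odds ratio was 0.800 without replicate 2. Germline markers were bound at 1 of 23, the helicase gene cgh-1 (187), and not at deps-1 or fbf-1 (odds ratio 0.180, adjusted p of 0.112 by the exact test), with odds ratios of 0.117 and 0.552 in windows of 500 and 2000 bp and 0.341 among the peaks of higher signal. Genes of the postembryonic mesoderm (M) lineage, in which SMA-9 acts, were bound at 5 of 19, led by egl-17 (151), ceh-20 (131.3) and hlh-1, with arg-1 and ceh-34 unbound (odds ratio 1.41, adjusted p of 0.647 by the exact test), and a 2000 bp window gave 0.936. Of the Hox genes ceh-13 (70.5) and nob-1 (66.2) were bound and egl-5 and lin-39 were not, 2 of 6. Their odds ratio was 1.98 (adjusted p of 0.474 by the exact test), and it was 3.97 without replicate 1. In a 500 bp window and among the peaks of higher signal 0 of 6 were bound. The values there, 0.423 and 0.577, had a constant added to each count. So did the germline value of 0.117 in a 500 bp window, where 0 of 23 were bound.

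Chemoreceptor genes were bound less often than other genes, at 30 of 1299 (2.31% against 21.4%, odds ratio 0.0867, adjusted p of 3.16e-87 by Fisher's exact test). The bound ones included srh-2 (803), srh-16 (398) and srh-17 (337), and sra-1 and sra-10 were unbound. With a 2000 bp window the odds ratio was 0.149.

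**Figure D4:**
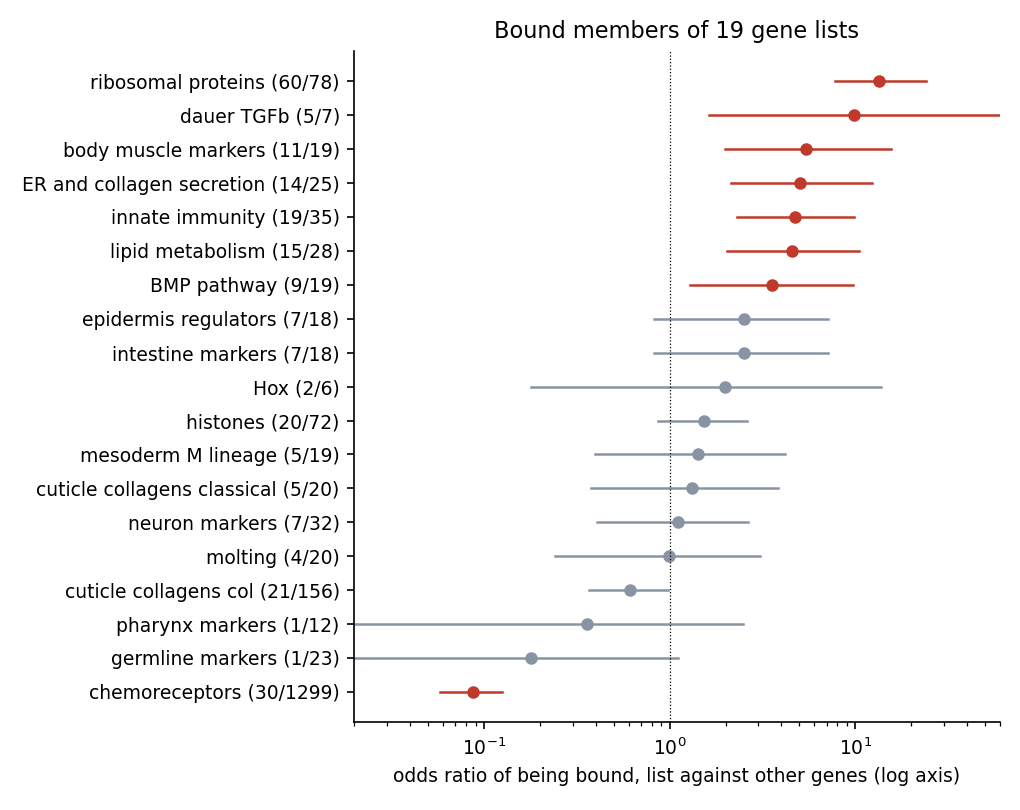
Odds ratio of being bound for 19 gene lists against other protein-coding genes (x axis, log scale), with points for the estimate, lines for exact 95% intervals that end at the axis limits, and bound and total members in brackets. Red marks the lists with an adjusted p under 0.05 by Fisher's exact test, from chemoreceptors at 0.0867 to ribosomal proteins at 13.4.

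Sequence at summits was compared with sequence 250 bp away. The Smad-binding core GTCT was found within 50 bp of 59.4% of summits and in 37.6% of flanking windows, with 2596 peaks holding it only at the summit and 1059 only in the flank (ratio 2.45, adjusted p of 3.41e-146 by the exact binomial test). The GC-rich Mad motif GRCGNC was at 21.8% against 9.10%. The composite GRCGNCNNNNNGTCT is patterned on the Mad, Medea and Schnurri site known from Drosophila. It was at 28 summits (0.396%) against 3 flanks (0.0425%), so few peaks held it (ratio 9.33, adjusted p of 5.98e-06, exact test). Its ratios were 14.5 without replicate 2, 17 among the peaks of higher signal and 5 (10 against 2, adjusted p of 0.0496, exact test) at summits outside 1000 bp of a 5' end. The palindrome GTCTAGAC was at 8 summits and 11 flanks and did not differ (adjusted p of 0.648, exact test). GATA sites (WGATAR) were at 36.4% against 22.1%, E-boxes of the sequence CACGTG at 7.36% against 1.61%, and TGACGT at 7.74% against 3.21%. The control 6-mer CAGTAC was at 2.26% against 2.12% (adjusted p of 0.648, exact test).

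The 5 best 6-mers that were more frequent at summits were GAGAGA (25.6% against 6.68%), AGAGAG (21.6% against 5.08%), AGAGAC (17.2% against 3.79%), CGTCTC (14.9% against 3.09%) and ACGCAG (12.2% against 1.94%). They overlap in part. CGTCTC contains GTCT, and so does AGAGAC, as GTCTCT on the other strand. GAGAGA and AGAGAG overlap each other. Whether GTCT was more frequent apart from these 6-mers was not tested. In all, 957 6-mers were more frequent and 521 less frequent at summits by the exact test, and the lowest were rich in A and T, such as AAAATT (13.8% against 41.2%). Summit windows had a GC content of 44.0% against 34.8% in flanks, so base composition differed between the windows. Against 4-mers with the same number of G and C, GTCT ranked 4 of 52, at 2.07 times their median ratio, which did not pass a two-sided exact rank test (p = 0.154). TGACGT ranked 20 of 640 6-mers and did not pass either (p = 0.0625, exact rank test), while CACGTG ranked 7 of 492 (p = 0.0285) and GAGAGA 3 of 640 (p = 0.00938). These rank p-values were not adjusted for the number of motifs compared. AGAGAG and AGAGAC ranked 2 and 1 of 640, but they had been picked as the best of all 6-mers, so their ranks are no separate test. GRCGNC, the composite, GTCTAGAC and WGATAR were not compared at equal GC.

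**Figure D5:**
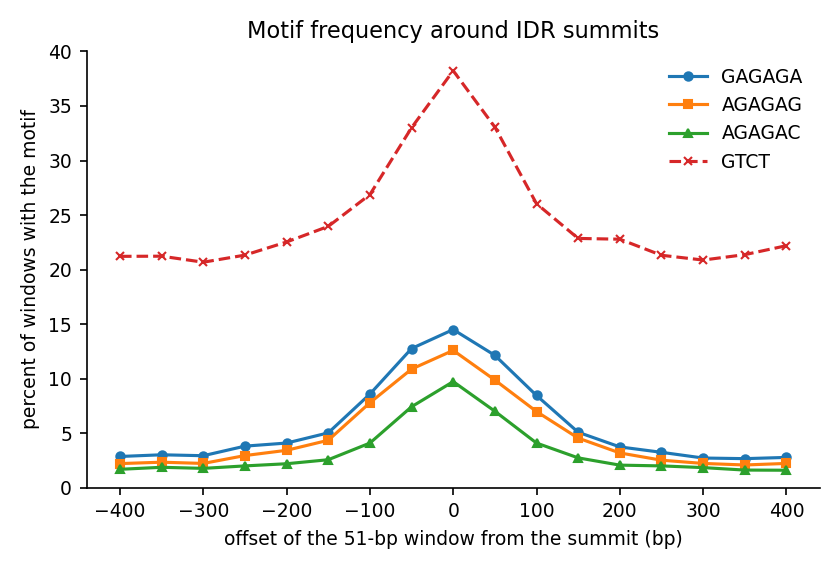
Percent of 51 bp windows that hold each motif on either strand (y axis) against the offset of the window from the IDR summit in bp (x axis). All 4 motifs, GAGAGA, AGAGAG, AGAGAC and GTCT, are most frequent at the summit. AGAGAC contains GTCT on its other strand, so their curves share sites.

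The lists on both builds were compared without converting coordinates. The IDR list held 6966 peaks on ce10 and 7065 on ce11, and 98.3% of the ce11 peaks had a ce10 peak on the same chromosome with the same width and a signal within 0.1%. For the pooled and replicate lists the share was 99.9%. The strongest signal, 2844 at dmd-7 on ce11, was also the highest signal in the ce10 list.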

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

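The tests in this part were chosen after the result was seen. Replicate 2's list held 17 peaks on the mitochondrial chromosome, which no comparison above used, with signals from 192 to 1591 and ranks from 1 to 330. The lists of replicate 1 and of both replicates together held 0 such peaks on either build, and the IDR list held none.

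A larger amount of mitochondrial DNA in the replicate 2 library may be a candidate cause of the 17 peaks, and with signals that sum it would leave calls in the pooled list, whose lowest signal was 16.5. Across IDR peaks called in both replicates the pooled signal was 0.994 times the sum (median), but nuclear peaks among the 7065 strongest of replicate 2 that overlapped no call of replicate 1 were also lost, with signals up to 173. Of such peaks among these 7065, 257 of 355 with a signal under 80 were in the pooled list and 12 of 25 with a higher signal, or 2 of 12 if calls of replicate 1 within 200 bp also counted, against 0 of the 17 (Fisher's exact test for the higher signals, p = 0.000499 and p = 0.163). Under 80 the difference from the 17 held by either match (257 of 355 and 191 of 275, Fisher's exact test, p = 8.99e-10 and p = 5.61e-09). For the higher signals it depended on how the peaks were matched. The 17 peaks lie on 1 chromosome and are not independent of each other, so these p-values count them as more evidence than they are. All of these nuclear peaks were weaker than the 17, so this cause stays open. A depletion of replicate 1 below the control, or another handling of that chromosome in some lists, stays open as well, and no biological explanation was tested.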

How the results depend on the processing

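Alternatives without the peaks at sma-9, with equal numbers of 5' ends, with equal GC and with distal summits, the variants of the 6-mers, chromosome centers by signal and by replicate, motifs by replicate and location classes by signal were added after the data were seen. So was the ce10 list as an alternative for the number of IDR peaks. Over all alternatives 213 values kept their direction and side of the threshold or stayed within their limits, 13 newly passed it, 10 no longer did, 6 values with no test moved and 18 turned their direction, with an adjusted p over 0.05 in both settings. The IDR list fell to 3532 peaks in the part of higher signal and the bound genes to 2348, by construction. Replicate overlap was 71.8% with summits within 100 bp, 63.1% with a reciprocal overlap of 50% and 76.3% with the 3532 strongest peaks of each, and the replicate correlation was 0.804 in the part of higher signal. The following are odds ratios, and the cause of each change was not tested. Where no member was bound, as for Hox with 500 bp and in the part of higher signal, a constant was added to each count. The BMP list without the sma-9 peaks has 1 bound member fewer, since sma-9 was kept in it as unbound. The BMP list lost its call with 500 bp (3.21), genes with a symbol (2.86), no peaks at sma-9 (2.88) and equal numbers of 5' ends (2.60). The dauer list lost it with 500 bp (4.12), the part of higher signal (5.63) and equal numbers of 5' ends (10.2), and the muscle list in the part of higher signal (1.41). With 2000 bp the col genes (0.648), the classical collagens (3.21), the epidermis and intestine lists (3.28 each) and the neuron list (2.32) passed. In the part of higher signal the col genes (0.351) and intestine markers (3.76) passed, and against genes with a symbol the col genes did (0.489). Odds ratios that crossed 1 were Hox (0.423) with 500 bp, the M lineage (0.936) with 2000 bp, the classical collagens (0.834), molting (1.33), Hox (0.577) and neuron (0.50001) in the part of higher signal, neuron (0.887) against genes with a symbol, molting (1.026) by upstream distance and neuron (0.831) with equal numbers of 5' ends. Motif ratios did so for GTCTAGAC (1.17) and CAGTAC (0.955) in wider windows and for CAGTAC in the part of higher signal (0.987) and at distal summits (0.820). GTCT was 2.07 times the median of 4-mers of equal GC and did not pass. Without replicate 1 or 2, the results whose call or direction changed ranged from 2.91 to 3.57 for BMP, 0.455 to 0.548 for the col genes, 2.53 to 4.01 for epidermis, 3.18 to 4.01 for intestine, 0.699 to 1.33 for the classical collagens, 0.915 to 1.12 for neuron, 0.991 to 1.0005 for molting, 0.889 to 1.14 for GTCTAGAC and 0.952 to 1.01 for CAGTAC. Ranges with a move of over 1.5 times but no change of call or direction were 2.001 to 3.97 for Hox, 0.360 to 0.800 for pharynx, 4.59 to 7.23 for lipid, 3.61 to 8.61 for muscle and 11.5 to 14.5 for the composite motif.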

Other observations

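The comparisons and tests in this part were chosen after the data were seen. There were 117 gene families of at least 15 members with a shared symbol prefix. By Fisher's exact test after adjustment, 14 were bound more often than other genes and 25 less often. Of these, 12 and 20 also passed a permutation test among genes with the same number of 5' ends. Genes with a symbol were bound at 24.0%, against 15.7% of the other protein-coding genes, and the families were not tested against that background. Besides the ribosomal families, the nuclear receptor genes (nhr) were bound at 102 of 269 members (37.9%, Wilson interval 32.3 to 43.8%), the glucuronosyltransferase genes (ugt) at 29 of 67 (43.3%), the heat shock genes (hsp) at 12 of 22 (54.5%) and the lin genes, named for cell lineage defects, at 22 of 47 (46.8%). The unc genes (35 of 94) and daf genes (11 of 26) passed the exact test but not the permutation test, with adjusted p of 0.196 for each by permutation. Most families bound less often were chemoreceptor families, such as str (5 of 193) and srh (9 of 220), and so restate the chemoreceptor list above. Others included the C-type lectins (clec, 21 of 240), the F-box genes fbxb (1.92% of members) and the FMRFamide-like neuropeptide genes (flp, 0 of 31).

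Several genes, chosen after their values were seen, had many IDR summits nearest to their 5' ends. They are not all of the genes with such counts, since T28B11.1 had 18 and dmd-6 had 16. The counts were not compared with the length of sequence nearest to each gene. The chromatin factor gene egl-27 had 20, the MAD-like gene mdl-1 had 17, the phosphatase gene vhp-1 had 17, the heterochronic gene lin-14 had 17, daf-16, the FoxO gene of insulin signalling, had 13, and daf-5 had 12. Among non-coding genes, 52.3% of 612 tRNA genes had an IDR summit within 1000 bp of their 5' end, against 13.3% ± 1.35 (SD of 200 draws) of random positions, and for 346 snoRNA genes the share was 44.8% against 11.5% ± 1.54. Of 15363 piRNA genes 5.69% had one, against 10.1% ± 0.248, and of 2128 pseudogenes 4.42% against 11.7% ± 0.719. These classes can lie in or next to protein-coding genes, which was not separated here, and they were not matched for expression.

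The higher density of peaks on X was weighed against a general property of the calling or the control. Among the 7500 lowest-ranked calls of the pooled list 23.63% lay on X (Wilson interval 22.7 to 24.6%), close to the 24.0% of IDR peaks and above the 17.7% of genome length, and the share was 22.9% among the 1000 strongest. An excess that is as large in the weakest calls is consistent with such a property, although weak calls may also hold binding. The amount of sequence near 5' ends was argued against, since within 1000 bp of protein-coding 5' ends the density on X was 1.504 times that of the autosomes. By genes, 26.03% of 2731 X-linked and 19.2% of 17242 autosomal protein-coding genes were bound. The design gives no biological contrast for X, so no biological explanation was tested.

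The cluster of strong peaks at sma-9 was weighed against extra copies of sma-9 sequence from the transgene, which could raise signal over the parts of the gene that it carries. The rest of the gene, 9917 bp downstream of the strong peaks, held 11 pooled calls, more than 95.6% of 1017 genes of at least that length, and more than 63.64% of the 11 of these that had a peak as strong within 3000 bp, a set narrowed after the first value was seen. The unc-119 gene (III 10902641 to 10908935), whose rescue copy the transgene carries, held 1 pooled call, an IDR peak at 10905218 to 10905487 with a signal of 114.2. Replicate 1 had 2 calls in this gene but none at the summit of that peak. The labels do not say which sma-9 or unc-119 sequence the transgene holds, and there was no worm without the transgene among the samples. Extra copies and binding of SMA-9 at its own gene therefore cannot be told apart from these lists.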
